A study of Mus musculus with 6 samples.

How the data were processed

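Poly(A) RNA was measured by strand-specific RNA sequencing in whole lung of 6 mice aged 6 weeks on the C57BL/6 background. Of these, 3 carried the Fra-2 transgene (Fra-2tg) and 3 were wild-type littermates. Fra-2 is the protein of Fosl2, a member of the AP-1 family of transcription factors. Libraries were made with a TruSeq stranded kit that marks the second cDNA strand with dUTP, per the labels' protocols. The labels differ on RNA quality. The extraction protocol gives RNA integrity numbers from 7.3 to 9, and the design text gives values over 8.

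Per the submitters' processing notes, FastQC, TopHat2 2.0.10, Bowtie 1.0.0, SAMtools 0.1.19 and Cufflinks 2.2.1 were used with the mouse build GRCm38 (mm10). The notes used here give no role, order or settings for these tools. The deposited table holds FPKM values from the authors for 23284 gene symbols in 6 columns, 1 for each mouse, and each column name matches the description of a single sample. FPKM is the number of fragments of a gene scaled to its transcript length and to the mapped fragments of the library. It is not a count, and no count model was applied. Whether counting used the strand, and how fragments shared by several genes were split, is not given in the sources used here. Values of paralogous, overlapping and nested genes are therefore uncertain.

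Symbols were used as in the table. Of 1025 different genes in 49 lists fixed before the data were examined, 1017 matched a row, 28 of them through an alternative or older symbol. The table uses Chi3l3 for Chil3, Chi3l4 for Chil4, Clca3 for Clca1, Igj for Jchain, Emr1 for Adgre1, Siglec5 for Siglecf and Faim3 for Fcmr. Coordinates come from the GENCODE annotation of GRCm38.

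The main test was limma 3.58.1 in R 4.3.3, two-sided, on log2(FPKM + 1) with a trend of the variance on the mean, over genes with a mean of at least 0.5 FPKM across the 6 libraries. Of the 23284 genes, 14855 were tested. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Ratios of means are ratios of the group mean FPKM. No covariate was fitted. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 45 lists with at least 5 tested members, and again with an estimated correlation. The test fry, run beside it, asks whether a list's genes move on balance in 1 direction and does not compare them with other genes.

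The genes named were chosen by a rule fixed before the data were examined. It takes the tested AP-1 genes and the 15 largest rises and 15 largest falls among called genes whose groups did not overlap, predicted genes and antigen receptor segments aside. It also takes up to 4 members with the smallest adjusted p of each list with a called change or at least 3 called members. The 3 most abundant members of lists for other tissues, other cell types, sex and sample handling were added, with the tested collagen VI chains, Col1a1, Col1a2 and Col3a1. Genes outside this rule are said to be so where they appear. A few genes that the rule names are not reported here.

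The procedure was tested on simulated data for this comparison, with 3 against 3 libraries drawn for 14855 genes, of which 200 were changed in each of 10 runs. It recovered 62.9% of genes changed 1.5-fold, 93.9% of those changed 2-fold and 97.6% of those changed 4-fold, all with the right sign. Of its calls, 5.13%, 4.43% and 4.97% were false. These folds were set on FPKM + 1, so in low genes they stand for larger changes of FPKM. Recovery of the same folds of FPKM itself was not measured for low genes. Of lists shifted by 0.5 on the log2 scale, 100% were called, and of lists not shifted 0.667%. These lists were random genes with values drawn independently of each other. The shares therefore do not give the rate of false calls for lists whose genes vary together.

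The number of reads behind each value is not given in the sources used here. The FPKM values of a library summed to 542233 to 664456 in wild type and 593094 to 646668 in Fra-2tg. Without Sftpc and Scgb1a1 these sums did not overlap, at 492782 to 518906 in wild type and 537215 to 593094 in Fra-2tg. Relative depth was estimated from genes below 0.15 FPKM, where values move in steps of 1 fragment. With wild type replicate 1 at 1, the estimates were 0.914 and 0.8 for wild type replicates 2 and 3, and 0.896, 1.19 and 1.36 for the Fra-2tg replicates. Between 21.2% and 26.5% of the low genes lay at these steps, so the estimates are rough.

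Alternatives set before the data were examined were pseudocounts of 0.1 and 0.01 FPKM, no filter and a filter at 5 FPKM, rescaling to equal library sums, median-ratio scaling, the replicate number as a block, robust moderation, library weights, no trend, and each library left out. A log2 fold change of at least 1, an adjusted p of 0.1 and camera with an estimated correlation were also among them. A fit with sex as a covariate was planned for mixed sexes and not run, because Xist was between 25.9 and 35.0 FPKM in all 6 libraries and no Y-linked gene on the list exceeded 0.0446 FPKM. Fits without Sftpc and Scgb1a1 and without small RNA genes were added after seeing the data. Principal components, correlations and the check of the replicate numbers leave out Sftpc and Scgb1a1. Python 3.11.15 and matplotlib 3.10.9 drew the figures.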

Results

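Lung RNA of 6-week-old mice was compared between 3 carriers of the Fra-2 transgene (Fra-2tg) and 3 littermates without it (wild type), to find the genes that differ between the genotypes. Each library is 1 mouse, and groups are as labelled. The first principal component, with 52% of the variance, separated the genotypes, and the second held 15%. On the first component the wild-type libraries lay at -30.4, -16.4 and -40.1 (replicates 1 to 3) and the Fra-2tg libraries at 27.0, 31.8 and 28.1. Wild type replicate 2 was therefore the wild-type library nearest to the Fra-2tg group. Correlations across genes were 0.971 to 0.974 within wild type, 0.976 to 0.981 within Fra-2tg and 0.936 to 0.963 between the groups. All 6 libraries carried Xist and next to no RNA of Y-linked genes. In the list of X and Y linked genes only Xist was tested, and 0 members were called (0 adjusted over the list alone).

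Fosl2, the gene of the transgene's protein, did not separate the groups, whereas its relative Fosl1 (Fra-1) did. Fosl2 (chromosome 5, 32135801 to 32157842) was 11.1, 13.9 and 11.2 FPKM in wild type and 12.3, 17.4 and 15.8 FPKM in Fra-2tg. Its means were 12.1 ± 1.60 FPKM in wild type and 15.2 ± 2.58 FPKM in Fra-2tg (SD, n = 3 each), a log2 fold change of 0.30 ± 0.14 (SE) with limma adjusted p = 0.158. The groups overlapped only in that wild type replicate 2 lay above Fra-2tg replicate 1. Without wild type replicate 2 the Fosl2 log2 fold change was 0.40, still not called (limma adjusted p = 0.101). Without Fra-2tg replicate 1 it was 0.43, not called either (limma adjusted p = 0.0576). Whether the table's Fosl2 row includes all transgene transcripts is not given in the sources used here, so this gene does not check the labels. Fosl1 (chromosome 19, 5447547 to 5455946) was 0.0271, 8.23 and 0.0631 FPKM in wild type replicates 1 to 3 and 39.9, 44.4 and 46.0 FPKM in Fra-2tg. Its log2 fold change was 4.36 ± 0.81 (limma adjusted p = 0.0103), and 5.41 without wild type replicate 2. Because 2 wild-type values lie near 0, the size depends on the pseudocount and was 7.27 with 0.01 FPKM. Of the AP-1 family list, 3 of 18 tested members were higher and 3 lower (3 and 3 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.931). Batf3, a factor of conventional dendritic cells, rose 2.58-fold (limma adjusted p = 0.00794). Fosb was at 0.202 times its wild-type mean, Jun at 0.766 and Jdp2 at 0.752 (limma adjusted p = 0.00397, 0.00511 and 0.0046). Jun and Jdp2 lost their calls with values rescaled to equal library sums (limma adjusted p = 0.0515 and 0.0686).

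**Figure D1:**
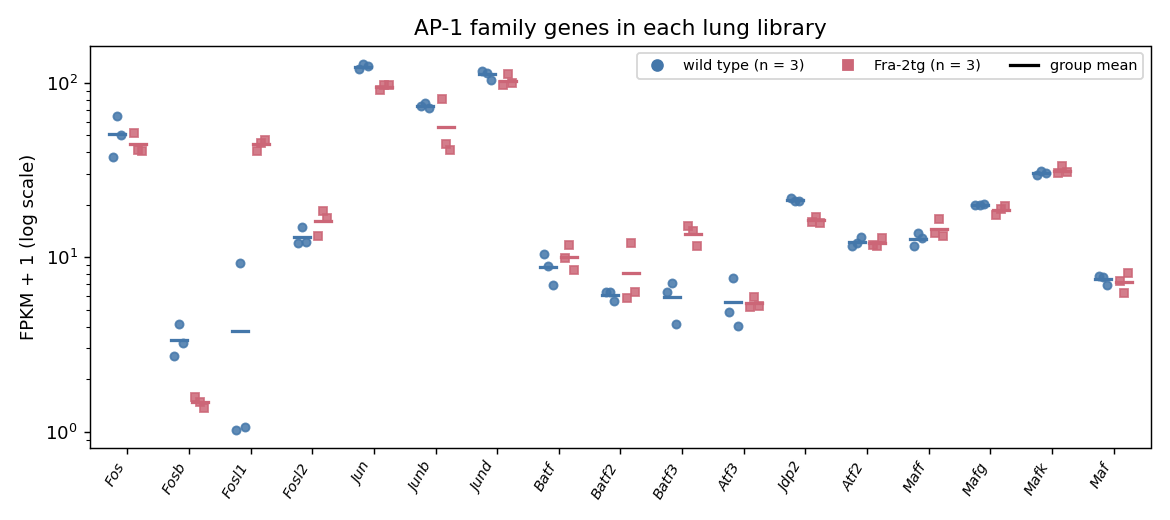
FPKM + 1 on a log axis for tested AP-1 family genes, with 1 point for each library (circles wild type, squares Fra-2tg) and a line at each group mean. Fosl1 lies near 0 FPKM in 2 wild-type libraries, at 8.23 FPKM in wild type replicate 2 and between 39.9 and 46.0 FPKM in Fra-2tg, while the Fosl2 values of the groups overlap.

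Across the transcriptome, 2027 genes were higher and 1936 lower in Fra-2tg, together 26.7% of the 14855 tested (limma, adjusted p under 0.05). Of these, 299 were higher and 259 lower by at least 1 on the log2 scale. The groups did not overlap for 45.7% of tested genes, where chance gives 10%. Retnla, a secreted product of alternatively activated macrophages and epithelium, had 981 ± 1263 FPKM in wild type and 12734 ± 4172 FPKM in Fra-2tg (SD, n = 3 each). The chitinase-like genes Chi3l4 and Chi3l3 rose 24.9-fold and 7.67-fold, and the eosinophil-associated ribonuclease Ear11 31.1-fold. The anion exchanger Slc26a4 rose 13.1-fold and the goblet cell gene Clca3 10.2-fold. Also among the largest rises were the chemokine Ccl17 (9.19-fold), the macrophage elastase Mmp12 (9.21-fold), Fbp1 (17.5-fold), Psca (11.4-fold) and R3hdml (13.5-fold). The size of these rises depends on wild type replicate 2, which held the highest wild-type value of each but Clca3. Retnla was 2437 FPKM there, against 324 and 182 FPKM in replicates 1 and 3. Fra-2tg replicate 2 held the highest Fra-2tg value of Retnla, Chi3l3, Ear11, Slc26a4, Clca3, Ccl17, Mmp12 and Fbp1, but not of Chi3l4, Psca or R3hdml. Ear11 was 129 FPKM there against 17.2 and 37.6 FPKM in Fra-2tg replicates 1 and 3. Large falls included Acoxl (0.0381 times the wild-type mean), Colq (0.0472), Fibin (0.0617), Itih4 (0.101), the retinoic acid hydroxylase Cyp26b1 (0.082), Zfp641 (0.0869) and Cst8 (0.00935). The endothelial genes Ednrb, an endothelin receptor, and Esm1 were at 0.164 and 0.0968 times wild type, myoglobin (Mb, highest of its group in Fra-2tg replicate 2) at 0.0959, and the B cell genes Faim3 and Igj at 0.088 and 0.0111. Lyz1 had 730.1 ± 64.7 FPKM in wild type and 146 ± 22.9 FPKM in Fra-2tg, and it shares sequence with its paralog Lyz2, so the split between them is uncertain.

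Leaving out 1 library ended the calls of Ear11 and Fbp1 (without wild type replicate 3, limma adjusted p = 0.0578 and 0.0641), Clca3 (without any Fra-2tg library, 0.0527 to 0.0673) and Igj (without wild type replicate 3 or any Fra-2tg library, 0.0515 to 0.0688). Robust moderation ended these calls and that of Psca (limma adjusted p = 0.0521 to 0.0801). Igj was 182 FPKM in wild type replicate 1 against 7.68 and 22.7 FPKM in replicates 2 and 3. The surfactant gene Sftpc (chromosome 14, 70520949 to 70524081) was listed at 0 in all 3 Fra-2tg libraries and at 25397, 33559 and 26567 FPKM in wild type. Scgb1a1, the club cell secretoglobin, is named after its values were seen (chromosome 19, 9083636 to 9087958). It was listed at 0 in wild type replicate 1 and Fra-2tg replicate 2. Elsewhere it was 111991 and 121243 FPKM in wild type and 74857 and 66105 FPKM in Fra-2tg. They reach the highest values in the table, and no other gene reaching 1000 FPKM has a 0, so no fold is given for either. The small RNA genes Snord49b, Mir719, Mir214 and Snord69, also among the largest changes, lie within the host genes 2410006H16Rik, Nupl1, Dnm3os and Gnl3 on the same strand and are uncertain in a poly(A) library. Snord49b was listed at 0 in all wild-type libraries, and of 199 small RNA genes tested 5 were called. Snord69 lost its call with each wild-type library left out and without Fra-2tg replicates 1 or 2 (limma adjusted p = 0.074 to 0.134). It also lost it with no filter (0.0685) and under both smaller pseudocounts (0.056 and 0.0618).

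**Figure D2:**
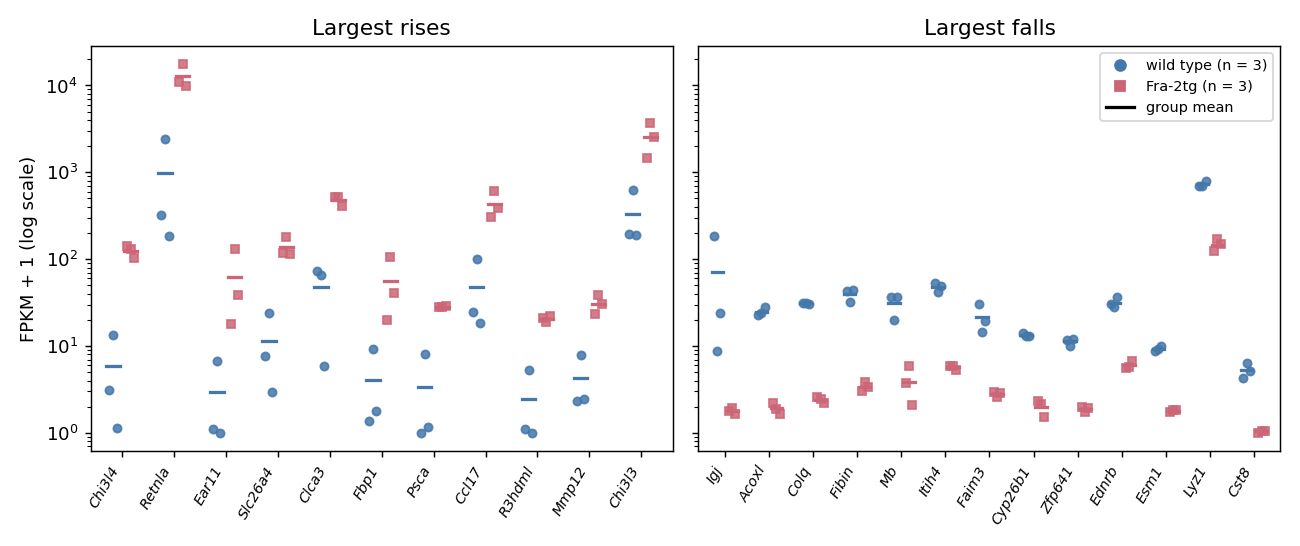
FPKM + 1 on a log axis for genes with the largest rises (left) and falls (right) in Fra-2tg, with 1 point for each library and a line at each group mean. Fosl1, small RNA genes and Sftpc are left out, and the groups do not overlap for any gene shown.

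The fibrillar collagen and basement membrane lists were called higher in Fra-2tg lung, each with some members lower. Among fibrillar collagens, Col3a1 had 227 ± 44.4 FPKM in wild type and 590.0 ± 64.8 FPKM in Fra-2tg (SD, n = 3 each), a rise of 2.59-fold (limma adjusted p = 0.00215), Col1a2 rose 2.03-fold, Col5a2 2.10-fold and Col1a1 1.58-fold. All 3 tested chains of collagen VI rose, Col6a1 1.62-fold, Col6a2 1.60-fold and Col6a3 1.34-fold (3 adjusted over the list alone). This list is too small for camera. Elastin (Eln) had 502 ± 135 FPKM in wild type and 1570.1 ± 83.6 FPKM in Fra-2tg, a rise of 3.13-fold, and the microfibril gene Mfap5 rose 2.87-fold. In the list of fibrillar collagens and their processing, 13 of 26 tested members were higher and 5 lower (14 and 6 adjusted over the list alone) (camera adjusted p = 0.0143; adjusted p = 0.642 with an estimated correlation). The lysyl hydroxylase Plod2, in the same list, fell to 0.543 of wild type. Of basement membrane and other collagens, 12 of 26 tested members were higher and 4 lower (13 and 4 adjusted over the list alone) (camera adjusted p = 0.0196; adjusted p = 0.731 with an estimated correlation). Col4a1 rose 1.93-fold, Col8a1 4.96-fold, Col15a1 3.01-fold and Col18a1 3.71-fold. In the list of matricellular and fibrosis-linked matrix genes, 14 of 30 tested members were higher and 6 lower (16 and 6 adjusted over the list alone) (camera adjusted p = 0.0296; adjusted p = 0.731 with an estimated correlation), with decorin (Dcn) at 0.573 times wild type. Of matrix metalloproteinases and inhibitors, 5 of 17 tested members were higher and 4 lower (6 and 4 adjusted over the list alone). Mmp2 and Mmp3 rose 2.67-fold and 2.91-fold and Mmp15 fell to 0.616 of wild type, and the list was not called (camera adjusted p = 0.37). TGF-beta signalling was not called either (camera adjusted p = 0.728; 6 of 23 higher and 4 lower, 7 and 4 adjusted over the list alone). Its members Bmp6, Smad6 and Smad7 were at 0.289, 0.516 and 0.552 times wild type. The Col1a1 call was lost without wild type replicates 1 or 3 or Fra-2tg replicates 1 or 3 (limma adjusted p = 0.0796 to 0.1) and Col6a3 without the same libraries (0.0977 to 0.114), with no filter (0.0587) and with no trend (0.0502). The basement membrane list lost its call without Fra-2tg replicate 3 (camera adjusted p = 0.108) and the matricellular list without Fra-2tg replicate 1 (0.0787) or with a filter at 5 FPKM (0.108). The replicate block also ended the calls of both lists (camera adjusted p = 0.063 and 0.0575) and of Col1a1 and Col6a3 (limma adjusted p = 0.085 and 0.0813).

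**Figure D3:**
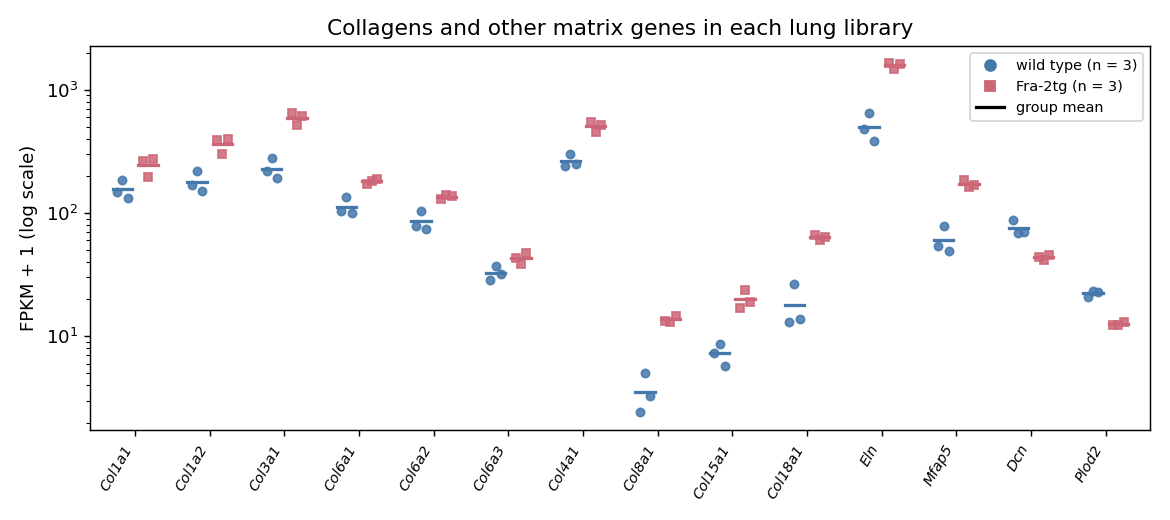
FPKM + 1 on a log axis for collagens and other matrix genes, with 1 point for each library (circles wild type, squares Fra-2tg) and a line at each group mean. Elastin rises 3.13-fold and Col3a1 2.59-fold, while Dcn and Plod2 are lower in Fra-2tg.

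The alternative macrophage, alveolar macrophage, dendritic cell and type 2 immunity lists were called higher, each with some members lower. These calls hold at the preset correlation and not with an estimated one. In the list of alternative macrophage activation, 13 of 21 tested members were higher and 2 lower (14 and 2 adjusted over the list alone) (camera adjusted p = 0.000127; adjusted p = 0.563 with an estimated correlation). The mannose receptor Mrc1 had 8.78 ± 1.53 FPKM in wild type and 24.2 ± 2.39 FPKM in Fra-2tg (SD, n = 3 each), a rise of 2.75-fold (limma adjusted p = 0.00147), the lectin Mgl2 rose 4.52-fold and the chemokine Ccl22 2.04-fold. Of alveolar macrophage markers, 14 of 21 tested members were higher and 2 lower (14 and 2 adjusted over the list alone) (camera adjusted p = 7.1e-05; adjusted p = 0.563 with an estimated correlation), with Itgax (CD11c) up 3.53-fold and Siglec5 1.97-fold. Monocyte and interstitial macrophage markers were not called as a list (camera adjusted p = 0.0681), although 11 of 22 tested members were higher and 4 lower (11 and 4 adjusted over the list alone). They were called higher without any 1 wild-type library (0.0207 to 0.0489) and rescaled to equal sums (0.0158). Among them Trem2 rose 3.56-fold, Ms4a7 3.58-fold, Cd68 2.64-fold and Emr1 (F4/80) 2.23-fold. For dendritic cell markers, 11 of 20 tested members were higher and 4 lower (11 and 4 adjusted over the list alone) (camera adjusted p = 0.0155; adjusted p = 0.694 with an estimated correlation). With a filter at 5 FPKM the call was lost (camera adjusted p = 0.0689). Itgae (CD103) rose 2.92-fold and Cd209a 2.35-fold. In the eosinophil and type 2 immunity list, 9 of 14 tested members were higher and 1 lower (9 and 2 adjusted over the list alone) (camera adjusted p = 0.0102; adjusted p = 0.563 with an estimated correlation). The cytokine Il13 had 0.129 ± 0.18 FPKM in wild type and 1.14 ± 0.119 FPKM in Fra-2tg, with the highest wild-type value in replicate 2, and Il1rl1, the receptor of interleukin-33, rose 2.23-fold, while Gata3 fell to 0.543 of wild type. MHC class II genes H2-Aa and H2-Eb1 rose 2.07-fold and 1.91-fold; 7 of 12 tested members were higher and 1 lower (7 and 3 adjusted over the list alone) (camera adjusted p = 0.0485; adjusted p = 0.731 with an estimated correlation). In the complement list, 6 of 16 tested members were higher and 2 lower (8 and 2 adjusted over the list alone) (camera adjusted p = 0.00904; adjusted p = 0.642 with an estimated correlation), with Hc (C5) up 2.45-fold, C1qb 2.98-fold and C3ar1 3.15-fold. Cfd, an adipocyte product, was at 0.254 times wild type. The type 2 list lost its call without Fra-2tg replicate 2 (camera adjusted p = 0.0764) or with a filter at 5 FPKM (0.266), and MHC class II lost its call without wild type replicate 2 or Fra-2tg replicates 2 or 3 (0.0916, 0.0699 and 0.0539) and under both smaller pseudocounts (0.0525 and 0.0522).

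The B cell, neutrophil, mast cell and interferon-response lists were called lower at the preset correlation and not with an estimated one. For B and plasma cell markers, 1 of 21 tested members were higher and 15 lower (1 and 17 adjusted over the list alone) (camera adjusted p = 6.14e-06; adjusted p = 0.58 with an estimated correlation). Cd79a had 68.7 ± 26.9 FPKM in wild type and 13.5 ± 3.41 FPKM in Fra-2tg (SD, n = 3 each), 0.196 times wild type (limma adjusted p = 0.00321). Wild type replicate 1 also held 40.4 FPKM of Glycam1, a gene of lymph node venules named after its values were seen, against at most 0.348 FPKM elsewhere. Without that library the B cell list was still lower (camera adjusted p = 1.68e-08). Of neutrophil markers, 0 of 16 tested members were higher and 7 lower (0 and 8 adjusted over the list alone) (camera adjusted p = 0.0196; adjusted p = 0.58 with an estimated correlation), with Csf3r at 0.29, S100a8 at 0.313 and S100a9 at 0.331 times wild type. This call was lost without Fra-2tg replicate 3 (camera adjusted p = 0.0513) or with a filter at 5 FPKM (0.0547). In the mast cell and basophil list, 0 of 5 tested members were higher and 3 lower (0 and 5 adjusted over the list alone) (camera adjusted p = 0.00229; adjusted p = 0.563 with an estimated correlation). The chymase Cma1 was at 0.206 times wild type, and Gata2, which endothelium also expresses, at 0.419. The list was not called with no filter (camera adjusted p = 0.0854). T and natural killer cell markers moved both ways (camera adjusted p = 0.736; 4 of 32 higher and 8 lower, 6 and 10 adjusted over the list alone). Klrb1c and Prf1 were at 0.0825 and 0.123 times wild type. Without wild type replicate 1 the list had 11 members higher and 6 lower. In the interferon response list, 0 of 28 tested members were higher and 18 lower (0 and 18 adjusted over the list alone) (camera adjusted p = 3.38e-05; adjusted p = 0.58 with an estimated correlation), with Oas2 at 0.244, Irf7 at 0.566 and Ifit1 at 0.65 times wild type. Classical macrophage and inflammatory cytokine genes were not called as a list (camera adjusted p = 0.474; 3 of 22 higher and 8 lower, 3 and 8 adjusted over the list alone). Osm and Ptgs2 were at 0.422 and 0.358 times wild type and Cd86 rose 2.04-fold. Lymphoid tissue and B zone chemokines (1 of 12 higher and 2 lower, 1 and 3 adjusted over the list alone) and MHC class I genes (0 of 18 higher and 0 lower, 0 and 0 adjusted over the list alone) were not called (camera adjusted p = 0.474 and 0.518). Without Fra-2tg replicate 2, MHC class I was called lower (0.00412).

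The alveolar type 1 and ciliated cell lists were called lower. Of alveolar type 1 genes, 1 of 20 tested members were higher and 12 lower (1 and 12 adjusted over the list alone) (camera adjusted p = 3.38e-05; adjusted p = 0.563 with an estimated correlation). Hopx had 1021 ± 32.6 FPKM in wild type and 623 ± 24.4 FPKM in Fra-2tg (SD, n = 3 each), 0.61 times wild type (limma adjusted p = 0.00215), Emp2 was at 0.524 and Vegfa at 0.546. Of alveolar type 2 markers, 10 of 20 tested members were higher and 2 lower (11 and 2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0681). Its median log2 fold change was 0.39 and its mean -0.43, a difference in sign that comes from Sftpc. Without Sftpc and Scgb1a1 the list was called higher (camera adjusted p = 0.0103), and without wild type replicate 2 (0.0073) or rescaled to equal sums (0.0254) as well. With all libraries and genes and an estimated correlation it was not called (camera adjusted p = 0.731). The cathepsin Ctsh rose 2.66-fold and Egfl6 2.88-fold, while Lyz1, also in this list, was at 0.2 times wild type. Airway secretory, goblet and basal markers split (6 of 21 higher and 6 lower, 7 and 7 adjusted over the list alone; camera adjusted p = 0.99). The secretory gene Bpifb1 rose 3.74-fold, whereas the club cell genes Scgb3a2, Cyp4b1 and Cyp2b10 were at 0.424, 0.426 and 0.424 times wild type. Ciliated cell markers were lower as a list with few members called (0 of 25 higher and 2 lower, 0 and 2 adjusted over the list alone; camera adjusted p = 0.000928; adjusted p = 0.731 with an estimated correlation), and Tppp3 was at 0.467 times wild type.

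Endothelial and fibroblast marker lists were lower while single members rose. Of endothelial markers, 3 of 33 tested members were higher and 18 lower (4 and 22 adjusted over the list alone) (camera adjusted p = 7.45e-06; adjusted p = 0.563 with an estimated correlation). Eng had 241 ± 14.4 FPKM in wild type and 116 ± 4.88 FPKM in Fra-2tg (SD, n = 3 each), 0.481 times wild type (limma adjusted p = 0.00064), Vwf was at 0.397 and Apln at 0.294. For fibroblast markers, 5 of 29 tested members were higher and 14 lower (6 and 18 adjusted over the list alone) (camera adjusted p = 0.00187; adjusted p = 0.58 with an estimated correlation). Fgfr4 and Pi16 were at 0.422 and 0.644 times wild type, and Dpt rose 1.95-fold. Smooth muscle and pericyte markers were not called as a list (camera adjusted p = 0.0544; 4 of 22 higher and 10 lower, 4 and 12 adjusted over the list alone), but were called lower without wild type replicate 1 or Fra-2tg replicate 2 (0.0307 and 0.0251), rescaled to equal sums (0.0434) and with library weights (0.0458). Desmin (Des) was at 0.639 times wild type, and the pericyte gene Rgs5 rose 4.86-fold. Mesothelial markers (4 of 17 higher and 5 lower, 4 and 5 adjusted over the list alone), nerve and glia markers (2 of 6 higher and 1 lower, 2 and 1 adjusted over the list alone) and wound and vascular remodelling factors (10 of 31 higher and 11 lower, 10 and 13 adjusted over the list alone) were not called (camera adjusted p = 0.384, 0.384 and 0.687). Within them the mesothelial gene Upk1b was at 0.262 times wild type, and the growth factor Igf1 and the plasminogen activator Plau rose 3.16-fold and 2.85-fold.

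A lung sample can carry RNA of heart muscle, skeletal muscle, fat and blood cells from adjoining tissue, vessels or blood. The lists of such genes were called lower in Fra-2tg at the preset correlation and not with an estimated one. Of cardiac and atrial muscle genes, 0 of 22 tested members were higher and 20 lower (0 and 21 adjusted over the list alone) (camera adjusted p = 4.5e-09; adjusted p = 0.563 with an estimated correlation). Its most abundant members Actc1 and Myl7 had 121 ± 15.1 FPKM in wild type and 34.4 ± 9.31 FPKM in Fra-2tg (SD, n = 3 each) and 104 ± 29.2 FPKM in wild type and 30.8 ± 11.9 FPKM in Fra-2tg, and Myl4 was at 0.333 times wild type. For skeletal muscle, 1 of 10 tested members were higher and 7 lower (1 and 7 adjusted over the list alone) (camera adjusted p = 0.00471; adjusted p = 0.563 with an estimated correlation), with Tcap at 0.246 and Eno3 at 0.627 times wild type and Tnni2 up 1.87-fold. With no filter this list was not called (camera adjusted p = 0.607), and without wild type replicate 1 it had 4 members lower. In the adipose and brown fat list, 0 of 14 tested members were higher and 10 lower (0 and 11 adjusted over the list alone) (camera adjusted p = 7.45e-06; adjusted p = 0.563 with an estimated correlation). Adrb3 and Pnpla2 were at 0.256 and 0.725 times wild type (limma adjusted p = 0.0019 and 0.00246), while Fabp4, which lung capillaries also express, had 45.3 ± 3.05 FPKM in wild type and 61.8 ± 21.4 FPKM in Fra-2tg (limma adjusted p = 0.221). Of erythrocyte and platelet genes, 0 of 13 tested members were higher and 5 lower (0 and 5 adjusted over the list alone) (camera adjusted p = 0.000232; adjusted p = 0.563 with an estimated correlation), a call lost with a filter at 5 FPKM (0.0547). The called members were platelet genes such as Ppbp and Itga2b, at 0.179 and 0.349 times wild type, whereas the globin Beta-s had 1201 ± 491 FPKM in wild type and 724 ± 84.6 FPKM in Fra-2tg (limma adjusted p = 0.11). Thymus genes (0 of 4 higher and 0 lower, 0 and 0 adjusted over the list alone) and those of oesophagus, trachea cartilage and thyroid (1 of 4 higher and 1 lower, 1 and 1 adjusted over the list alone) had too few tested members for camera. The squamous gene Sprr1a, in the latter, rose 5.19-fold, with the highest wild-type value in replicate 2, a call lost without wild type replicate 3 (limma adjusted p = 0.0524).

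The proliferation and oxidative phosphorylation lists were called higher, with most of their members not called. In the proliferation list, 9 of 35 tested members were higher and 0 lower (9 and 0 adjusted over the list alone) (camera adjusted p = 2.22e-06; adjusted p = 0.694 with an estimated correlation). Mcm6, a replication helicase subunit, had 14.6 ± 2.60 FPKM in wild type and 25.1 ± 2.45 FPKM in Fra-2tg (SD, n = 3 each), a rise of 1.71-fold (limma adjusted p = 0.00854), and Tk1 rose 2.07-fold. The number of higher members was 31 without wild type replicate 1 and 3 without wild type replicate 2. For oxidative phosphorylation, 9 of 32 tested members were higher and 0 lower (11 and 0 adjusted over the list alone) (camera adjusted p = 1.81e-05; adjusted p = 0.69 with an estimated correlation), with a median log2 fold change of 0.19. Without wild type replicate 1, and without replicate 2, 4 members were higher. Atp5c1 rose 1.28-fold and Uqcrb 1.30-fold, calls lost with values rescaled to equal library sums (limma adjusted p = 0.0727 and 0.085). Glycolysis and hypoxia (9 of 23 higher and 4 lower, 12 and 4 adjusted over the list alone), cholesterol synthesis (1 of 22 higher and 2 lower, 1 and 1 adjusted over the list alone) and fatty acid and surfactant lipid synthesis (3 of 23 higher and 8 lower, 3 and 8 adjusted over the list alone) were not called (camera adjusted p = 0.0986, 0.964 and 0.154). The last was called lower without wild type replicate 1 (0.0187). Neither were the unfolded protein response (3 of 22 higher and 1 lower, 2 and 1 adjusted over the list alone) and NRF2 and xenobiotic metabolism (4 of 23 higher and 8 lower, 5 and 8 adjusted over the list alone; camera adjusted p = 0.361 and 0.341, the latter 0.0145 and lower without Fra-2tg replicate 2). Ldha rose 1.57-fold and Hmox1 1.67-fold, and Fmo1 was at 0.322 times wild type. Lists that follow sample handling were not called. They were immediate early and dissociation stress genes (4 of 27 higher and 3 lower, 5 and 4 adjusted over the list alone), the circadian clock (1 of 18 higher and 3 lower, 1 and 2 adjusted over the list alone) and the glucocorticoid response (4 of 15 higher and 0 lower, 4 and 0 adjusted over the list alone), with camera adjusted p = 0.994, 0.628 and 0.191. The glucocorticoid list was called higher without Fra-2tg replicate 1 (0.0156). The log2 fold changes of Fkbp5 and Bhlhe40 were 0.76 and 0.93, and Dusp1 had 172 ± 69.8 FPKM in wild type and 149 ± 36.1 FPKM in Fra-2tg (limma adjusted p = 0.706).

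In all, 11 of the 45 lists were called higher and 12 lower at the preset correlation, and 0 and 0 with an estimated correlation, where 3 lists had an unadjusted p under 0.05. Lists not called in the reported fit but called in an alternative had camera adjusted p of 0.563 to 0.918 in the reported fit with an estimated correlation. By fry, 19 lists moved in 1 direction, 6 up and 13 down. The 13 include the alveolar type 2 list, in which Sftpc is listed at 0 in Fra-2tg and 15 of the 19 other members had a log2 fold change above 0. Without wild type replicate 1, the members higher and lower were 6 and 5 for classical macrophage genes, 10 and 5 for airway markers, 10 and 1 for complement, 3 and 4 for TGF-beta signalling, 10 and 2 for fibrillar collagens, 11 and 2 for basement membrane, 10 and 2 for monocyte markers, 1 and 0 for the unfolded protein response and 2 and 0 for glucocorticoid response. Without wild type replicate 2 they were 2 and 8 for classical macrophage genes, 3 and 5 for airway markers, 3 and 6 for smooth muscle, 7 and 4 for immediate early genes, 4 and 4 for TGF-beta signalling, 4 and 1 for cholesterol synthesis and 13 and 2 for fibrillar collagens. In that fit they were also 6 and 2 for matrix metalloproteinases, 1 and 0 for the unfolded protein response and 2 and 1 for glucocorticoid response. Apart from counts given above, moves by over 1.5 times in other lists were by 1 gene in these fits. Members were not counted without the other libraries. In 8 of the 45 lists the median, the mean and the camera direction were not of 1 sign. Of these, 7 had a camera adjusted p of 0.474 or more, and the other was the alveolar type 2 list.

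**Figure D4:**
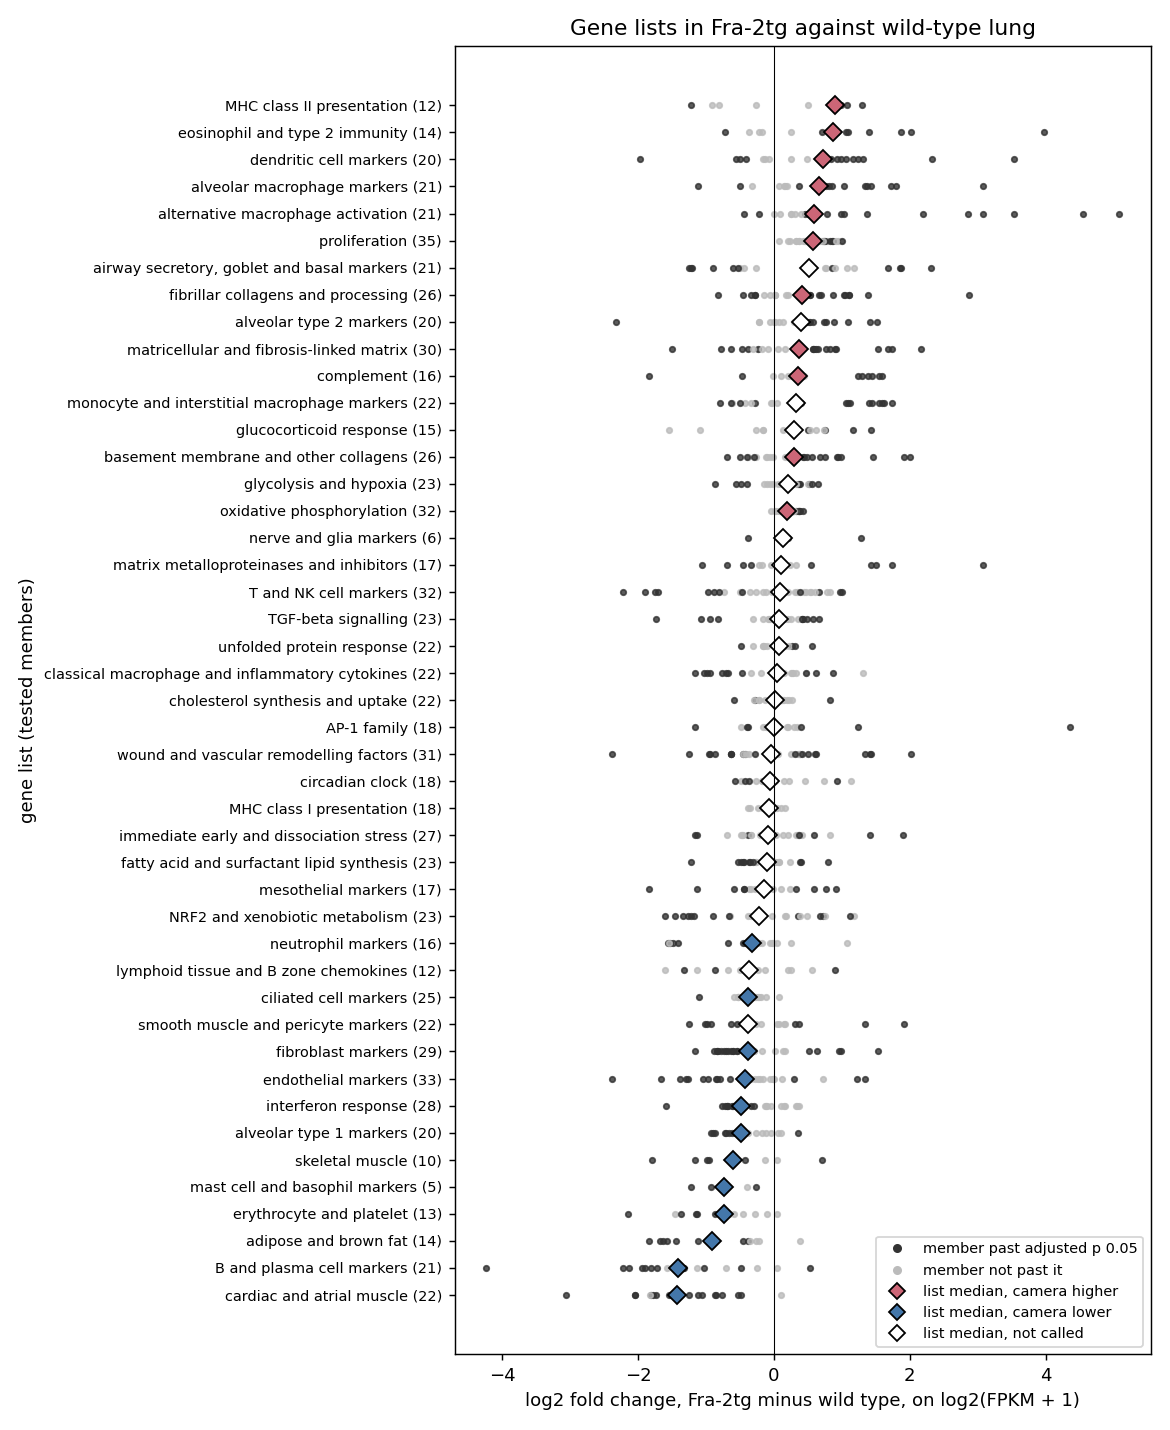
Log2 fold changes of the members of each of the 45 tested lists (small points, dark where called) and the median of each list (diamonds), Fra-2tg minus wild type on log2(FPKM + 1). Sftpc and Scgb1a1 are not drawn but count in the medians, and the lowest median belongs to cardiac and atrial muscle (-1.43).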

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

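The fits without Sftpc and Scgb1a1 and without small RNA genes were chosen after seeing the data, and all other alternatives before. The counts of 2027 genes higher and 1936 lower stayed within 1.5 times under both pseudocounts, both filters, median-ratio scaling, robust moderation, library weights, no trend, an adjusted p of 0.1 and both added fits. Rescaled to equal library sums, 1164 genes were higher and 1213 lower, of which 1132 and 1171 were among those reported. The cause was not tested, but those totals include Sftpc and Scgb1a1, which are listed at 0 in some libraries. With these genes, wild type replicates 1 to 3 summed to 542233, 664456 and 640592 FPKM, and without them to 516836, 518906 and 492782 FPKM. The zeros therefore move this scaling, which limits all calls lost or gained under it. With a log2 fold change of at least 1, the counts were 299 and 259 by construction. Leaving out 1 library gave 1088 to 1695 genes higher and 1141 to 1709 lower, with 5 libraries in the fit. The lowest values came without wild type replicate 3 (1088 and 1141), and 1158 genes were higher without Fra-2tg replicate 1. Without wild type replicate 2 they were 1627 and 1517, of which 1512 and 1444 were among those reported. The Fosl2 log2 fold change ranged from 0.19 to 0.43 and was not called in any alternative run (limma adjusted p = 0.0576 to 0.362).

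The list counts of 11 higher and 12 lower stayed within 1.5 times in every alternative but one, camera with an estimated correlation, which called 0 and 0 at adjusted p of 0.563 or more. Of the 194 called genes named by the rule, 13 to 26 lost their call without 1 library, 30 of them without at least 1 library, and 5 of the 23 called lists did so. No gene or list named changed sign where either fit called it. With the filter at 5 FPKM, only 21 of the 23 called lists kept enough members to be tested. Of these, 5 lost their call (matricellular, dendritic cell, neutrophil, type 2 immunity, and erythrocyte and platelet, camera adjusted p = 0.0547 to 0.266). Rescaling to equal sums added 3 list calls, monocyte (0.0158), alveolar type 2 (0.0254) and smooth muscle (0.0434). With no filter 2 ended, mast cell (0.0854) and skeletal muscle (0.607). Robust moderation ended 8 calls of named genes (Ear11, Clca3, Fbp1, Psca, Igj, Snord69, Mt1 and Mt2) and rescaling 19. Rescaling to equal sums turned the sign of the medians of 2 lists too small to test, thymus and oesophagus, trachea cartilage and thyroid.

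With the replicate block, 1890 genes were higher and 1651 lower, of which 1670 and 1558 were among those reported, and 9 lists were higher and 13 lower. Smooth muscle was called in that fit (camera adjusted p = 0.0438). Not called in it were the basement membrane and matricellular lists (camera adjusted p = 0.063 and 0.0575), and Col1a1 and Col6a3 (limma adjusted p = 0.085 and 0.0813). Whether the numbers pair the samples stays open, since 3 libraries in each group are too few to settle it. The deviations of same-numbered libraries correlated at 0.0148 to 0.132 across genes, against -0.168 to 0.0793 for differently numbered ones. Of the 6 libraries, 4 correlated best with their own number. Without read totals, counting error could not be set beside these spreads, and genes near 0.5 FPKM are the least certain.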

Other observations

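The gene families in this part and all tests but the counts of other splits were chosen after the values were seen. Of 12 tested S100 genes, 7 were higher and 2 lower in Fra-2tg (5 and 2 with values rescaled to equal library sums). S100a4 had 116 ± 56.4 FPKM in wild type and 578 ± 71.6 FPKM in Fra-2tg (SD, n = 3 each) and S100a6 441 ± 183 FPKM in wild type and 1543 ± 133 FPKM in Fra-2tg, while the neutrophil genes S100a8 and S100a9 were the 2 lower ones. Of 18 CC chemokine genes, 9 were higher and 2 lower (9 and 1 rescaled). Ccl9 rose 4.12-fold, Ccl6 3.11-fold and the eosinophil attractant Ccl11 3.19-fold, whereas Ccl3 and Ccl4 were at 0.542 and 0.297 times wild type. Of 9 galectin genes, 2 were higher and 2 lower (2 and 1 rescaled), with Lgals1 up 3.38-fold and Lgals3 2.64-fold. All 5 tested flavin monooxygenases were lower (5 of 5 under each scaling), from 0.322 times wild type for Fmo1 to 0.647 for Fmo5. Among IGF-binding proteins, Igfbp3 was at 0.216, Igfbp4 at 0.529 and Igfbp2 at 0.531 times wild type, and Igfbp5 rose 1.33-fold, a call not kept when rescaled.

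Wild type replicate 2 lay part of the way from the other wild-type libraries to the Fra-2tg mean, at a median of 0.221 of that distance over 671 genes (quartiles 0.15 and 0.308), against -0.142 to 0.036 for each other library. For wild type replicates 1 and 3 (-0.037 and -0.142) the starting point includes replicate 2 itself, so their shares are not an independent reference. A mislabelled Fra-2tg library would lie near 1, but rising genes steady in the other wild-type libraries lay at 0.22 (142 genes, quartiles 0.189 and 0.262). RNA or reads of Fra-2tg tissue mixed into this library stays open as a candidate explanation, since rising and falling genes would then lie at equal shares, and the medians of steady genes of at least 10 FPKM differed by 0.00854. Over all 370 rising and 301 falling genes the medians were 0.204 and 0.278, a difference of 0.074. That test was changed after its outcome was seen. As first written it covered all genes near 0 in the other wild-type libraries and went against a mixture, because 7 small RNA genes lay at -9.59e-05 to 1.81; these were then left out, and the other 10 lay at 0.0939 to 0.27. A stricter limit for steady genes had also been looked at before the limit used, so the result carries little weight. A mixture alone does not account for the B cell and cardiac lists, at 0.586 and 0.587, nor for monocyte and complement genes, at 0.135 and 0.111. In all, 5 of 21 lists had quartiles wholly outside those of the steady rising genes. A milder change in the animal itself cannot be told apart from a mixture for the rest. List medians span 0.476, or 0.245 without the B cell and cardiac lists, and nothing here fixes the span such a state would give.

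Sftpc and Scgb1a1 are listed at 0 in 5 of 12 values although they are otherwise the most abundant genes. Fewer alveolar type 2 cells would lower the other markers of these cells, but their median log2 fold change was 0.485 (quartiles 0.0111 and 0.748), with 15 of 19 above 0. Failed estimates for the most abundant genes in the submitters' processing remain a candidate cause, as 0 of the other 89 genes that reach 1000 FPKM has a 0 in any library and the Scgb1a1 zeros fall in 1 library of each group. A loss of Sftpc RNA alone stays open, since its zeros follow the genotype.

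Markers of alveolar type 1, ciliated, endothelial, fibroblast and smooth muscle cells had medians from -0.49 to -0.38, which could come from dilution by RNA of other cells. A common dilution would lower all 128 members, by about the common median of -0.39 if they moved alike. For 50.8% the 95% interval excluded this median, 31 above and 34 below, where 5% is the share by chance. The log2(FPKM + 1) scale shrinks the shift of low members, so this share alone does not decide against dilution. Of fibroblast markers 5 of 29 were called higher and 14 lower, and of smooth muscle markers 4 of 22 and 10. Dilution by cells without these genes would raise none. A lower share of each cell type by its own amount meets the same limits, with 47.3% of members off the median of their own list. Neither accounts for the whole pattern, as some members rose. Dilution of part of it, beside changes of expression within cells, stays open, and the genotype is the biological difference in the design.

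The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split was the 1 with the most calls, 3963 genes against at most 4 in another split. For lists the real split gave 23, the highest of the 10, but the others, which mix the genotypes, gave 5 to 20. The number of lists called at the preset correlation therefore hardly sets the real split apart.

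Lyz2, Nppa and Lgals6 were chosen after their values were seen. Lyz2, the paralog of Lyz1, was 3934, 4060 and 4393 FPKM in wild type and 1204, 1570 and 1353 FPKM in Fra-2tg. Nppa, the atrial natriuretic peptide, was 24.2, 3.02 and 13.5 FPKM in wild type and 1.39, 5.17 and 1.25 FPKM in Fra-2tg. Lgals6, a galectin gene, was 3.25, 2.11 and 1.01 FPKM in wild type and at most 0.00117 FPKM in Fra-2tg.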
